A study of Mus musculus with 6 samples.

How the data were processed

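RNA was sequenced from mouse glioblastoma (GBM) neurosphere cultures, 3 libraries with the genotype ATRX knockout (ATRX KO) and 3 with ATRX wild type (ATRX WT). Per the labels, tumours were started in the ventricles of neonatal mice, C57BL/6 or FVB, with Sleeping Beauty transposon plasmids that carry a short hairpin against p53, NRAS, and, with or without it, a short hairpin against ATRX. The labels call the same libraries a knockout, so both forms are given and which was used is not known. Which mouse strain each line came from is not stated. All libraries of a genotype share 1 line code in their titles, so genotype and line cannot be told apart in this design. Cells grew in neural stem cell medium with B-27, N-2, FGF and EGF. Libraries were made from 4 ug of total RNA with a stranded mRNA kit and read as paired-end 42-nt reads.

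The authors deposited 1 table of log2 RPKM values, that is, log2 reads per kilobase of gene scaled to library size, for 13069 genes in 6 columns. Per the submitters' processing notes the tools were FastQC, Trim Galore, STAR 2.5.3a, HTSeq 0.11.2 and edgeR 3.20.9. The notes name the builds mm9 and mm10 without a role for either, and the filter that removed low genes from the table is not stated. In each library the deposited log2 values fell on whole-read steps above a floor, with a prior count that averaged 2 reads over the libraries and scaled with library size. Whole reads were recovered from these steps for 100% of genes, with a tolerance of 0.0001 reads, and log2 RPKM rebuilt from them differed from the deposited values by at most 5.3e-14. The same recovery returned the true reads and gene lengths for 100% of 13069 genes in simulated data. Reads in the table numbered 32477269, 27998458 and 22177228 in ATRX KO replicates 1 to 3 and 34966108, 38039847 and 37004282 in ATRX WT replicates 1 to 3. The library sizes the authors scaled by were 0.932 to 0.935 of these totals in ATRX KO and 1.068 to 1.073 of them in ATRX WT.

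Genes with log2 RPKM of at least 0 in at least 3 of the 6 libraries were tested, which kept 12201 genes and left out 868. The deposited log2 RPKM values were fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, 4 residual and 4.2 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A gene is said to have risen or fallen in ATRX KO when it passed that threshold. Fold changes are ATRX KO minus ATRX WT on the log2 scale with their standard error (SE), and group values are means with the standard deviation (SD) over 3 libraries. Where a group held 0 reads over its libraries, the fold is a lower bound against 3 reads over the group, and where it held 1 to 3 reads, a ratio of summed reads over summed library sizes is given with its 95% counting interval. Intervals and floors cover counting error only, and p-values measure the spread between these libraries, which may be technical, since all libraries of a genotype come from 1 line.

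Before the data were examined, 30 gene lists were fixed, together with the genes to name. The primary lists were S phase, G2/M, and checkpoint kinases with other regulators of phase transition. The secondary lists covered DNA repair, p53 targets, ATRX partners and telomere, Polycomb and DNA methylation enzymes, Hox and imprinted genes, interferon and MHC class I, neural and mesenchymal cell states, RAS-MAPK output, hypoxia, stress, immediate early genes and cholesterol synthesis. Further lists covered RNA quality, other cell types and sex. Lists with at least 5 tested members, 25 of the 30, were tested with limma's camera against all other tested genes with a preset correlation between genes of 0.01 and adjustment over the 25 lists. Camera with an estimated correlation and the rotation test fry were run beside it. The rule for named genes took the targeted and model genes whatever their result, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose higher group reaches log2 RPKM 2, without predicted genes, and up to 2 members per list each way, or 4 for the primary lists. Genes named outside that rule are said to have been chosen after their values were seen. Coordinates are from GENCODE M21 (GRCm38), which gave 1 position for 12619 of the 13069 symbols, left out 1 symbol that matched more than 1 gene, and had no match for 449.

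The test was checked on simulated data with the read depths of these libraries and 11869 genes. It recovered 46 of 49 genes changed by log2 0.5 (93.9%) and 100% of those changed by log2 1, 2 or 4, and 9 of 204 calls were false (4.4%). Among 95 simulated lists without a change, 0 had an unadjusted p under 0.05 in camera, and a shifted list gave adjusted p = 3.4e-56. The simulated genes were drawn independently of each other, and most were unchanged. These checks therefore cannot show the rate of false calls, for genes or lists, where genes move together and most differ. Alternatives changed the filter, the pseudocount, the scaling between libraries, the variance model, library weights, the threshold, the set test and a block for replicate number, and left out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, scaling by the reads in the table, reads thinned to the depth of the shallowest library, and a fit without genes on chromosomes 4 and 16. Raw reads were not mapped again, so splice forms, the plasmid transcripts and the sequence of the ATRX locus were not examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery, the tests along the genome and the figures.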

Results

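RNA-seq profiles were compared between cultures labelled as mouse GBM neurospheres with the genotypes ATRX knockout and ATRX wild type. ATRX is a chromatin remodeller that places histone H3.3 at telomeres and other repeats. Each genotype had 3 libraries, with 22177228 to 32477269 reads in the table in ATRX KO and 34966108 to 38039847 in ATRX WT. The series title names the question the comparison addresses, whether loss of ATRX alters the passage of glioma cells between phases of the cell cycle. The top 50 genes took 10.6% to 10.7% of reads in ATRX KO and 9.4% to 9.6% in ATRX WT. Pearson correlations across genes were 0.997 to 0.998 within a genotype and 0.662 to 0.668 between genotypes. These correlations are across genes, which are not independent replicates. The spread of a pair of libraries was also compared with counting error, as a chi-square per degree of freedom. It was 7.24 for ATRX KO replicates 1 and 2, 3.89 for 1 and 3, and 2.28 for 2 and 3. In ATRX WT it was 1.89 to 2.93, so ATRX KO replicate 1 stood furthest from the others of its group.

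Atrx transcript was lower in ATRX KO but present in every library. It stood at 14.1, 16.6 and 17.1 RPKM in ATRX KO replicates 1 to 3 and at 22.3, 22.7 and 21.6 RPKM in ATRX WT replicates 1 to 3. The group means were 16 ± 1.6 and 22.2 ± 0.571 RPKM (SD, n = 3 each), so ATRX KO held 71.7% of the ATRX WT level. Atrx (ENSMUSG00000031229.16, chromosome X, 105797615 to 105929403, GRCm38) fell by 0.48 on the log2 scale (SE 0.068, limma adjusted p = 0.00013), and every ATRX KO library lay below every ATRX WT library. Of all tested genes 89.5% passed between these lines, so the fall of Atrx cannot be assigned to its targeting. A gene's read total cannot show whether its transcripts still encode protein. Trp53, the tumour suppressor targeted by the short hairpin in both genotypes, stood at log2 RPKM 3.56 ± 0.07 in ATRX KO and 3.69 ± 0.02 in ATRX WT, a log2 difference of -0.13 (adjusted p = 0.018). That call was lost without ATRX KO replicate 3 and without ATRX WT replicate 3, each at adjusted p = 0.063, the highest of a range that began at 7.4e-05 over the alternatives. Nras, the oncogene the tumours were started with, rose from 121 ± 0.835 to 177 ± 4.73 RPKM (log2 fold change 0.55, SE 0.028, adjusted p = 1e-07). The table does not separate plasmid from endogenous Nras, and its relative Hras, chosen after its value was seen, fell by 0.30.

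Of the kinases that stop the cycle after DNA damage, Chek1 fell, while Atm and Atr differed by less. Chek1 (ENSMUSG00000032113.16, chromosome 9, 36708482 to 36727065), which restrains entry into mitosis when replication is incomplete, went from log2 RPKM 3.84 ± 0.06 in ATRX WT to 3.18 ± 0.06 in ATRX KO. In RPKM, ATRX KO held 63.3% of the ATRX WT level (log2 fold change -0.66, SE 0.048, adjusted p = 1.2e-06). Atm, the kinase that senses double-strand breaks, differed by -0.16 (SE 0.049, adjusted p = 0.012), with adjusted p = 0.054 without ATRX WT replicate 2 and 0.21 after quantile normalization, in a range of 9.3e-05 to 0.21. Atr, the kinase that senses stalled forks and acts upstream of Chek1, stood at 3.13 ± 0.09 against 3.06 ± 0.02 and did not pass the test (log2 difference 0.08, adjusted p = 0.2). Without ATRX KO replicate 1 Atr was higher by 0.13 (adjusted p = 0.023, in a range of 0.023 to 0.54), and with library size taken as the reads in the table it was lower by a log2 difference of -0.12.

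Genes that act in DNA replication were lower in ATRX KO. Of the 43 S phase genes tested, 9 rose, 32 fell and 2 gave no call, with a median log2 fold change of -0.42. Clspn, the adaptor through which Atr activates Chek1, fell from log2 RPKM 4.81 ± 0.01 to 2.95 ± 0.06 (log2 fold change -1.87, SE 0.041). Rrm2, a subunit of the enzyme that makes deoxynucleotides, fell by 1.32, Wdr76 by 1.49, and Dscc1, which helps load the replication clamp, by 1.30. E2f8, a repressor of E2F target genes, rose by 1.58 (SE 0.033), and the other largest rises were Usp1 with 1.15, the histone chaperone Nasp with 0.86 and Cdca7 with 0.50. The list as a whole was lower than other genes in camera (adjusted p = 0.0056), and had adjusted p = 0.18 with an estimated correlation. In the same libraries matrix and mesenchymal genes were higher (median log2 fold change 3.75) and neuronal genes lower (median -3.79), so the cell cycle lists moved beside markers of cell type.

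Genes of G2 and mitosis moved the same way. Of 54 G2/M genes tested, 6 rose, 42 fell and 6 gave no call, with a median of -0.50. The largest falls were Ckap2, a microtubule-associated protein of the spindle (log2 fold change -1.22, SE 0.043), Ttk, the spindle checkpoint kinase (-1.11, SE 0.036), Nusap1 (-1.11) and Ckap2l (-1.09). Rises were seen for Cks1b, a partner of cyclin-dependent kinases (0.88), Lbr (0.82), Kif2c (0.54) and Anln (0.50). Nasp, Kif2c and the kinase Plk3 lie in a stretch of chromosome 4, 110 to 120 Mb, whose 42 genes with a mean log2 RPKM of at least 3 had a median of 1.30. The S phase gene Usp1 lies at 90 to 100 Mb of that chromosome, where 7 such genes had a median of 1.15. For the G2/M list camera gave adjusted p = 0.00016, and adjusted p = 0.15 with an estimated correlation. Chosen after their values were seen, the proliferation marker Mki67 fell by 0.53, Cdk1 by 0.32 and the mitotic brake Wee1 by 0.51, while cyclin D1, Ccnd1, fell from 671 to 410 RPKM. For every list, the numbers of genes that rose and fell adjusted over the list alone equalled those over all genes tested.

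Checkpoint kinases and phase-transition regulators moved apart. Among the 49 tested, 14 rose, 31 fell and 4 gave no call, so the median was -0.34 while the mean was 0.08. The largest rises included inhibitors of G1 kinases. Cdkn2b, the p15 inhibitor of Cdk4 and Cdk6, had 3505 reads in ATRX KO and 0 in ATRX WT, at least 1780-fold higher, while Mtap in the same part of chromosome 4, chosen after its value was seen, stood at 152 against 161 RPKM. Plk3, a stress-responsive kinase, rose by 4.79 (SE 0.041), Cdkn1c, the p57 inhibitor, by 3.85, and Cdk6 by 3.08. Falls included Rb1, the retinoblastoma brake on S phase entry (log2 fold change -1.54, SE 0.077), the inhibitor Cdkn2d (-1.79), Clspn and Ttk. The list did not pass camera (adjusted p = 0.081, and adjusted p = 0.32 with an estimated correlation). The p53 target Cdkn1a (p21) and the kinase Chek2, both chosen after their values were seen, fell by 0.29 and 0.81.

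**Figure D1:**
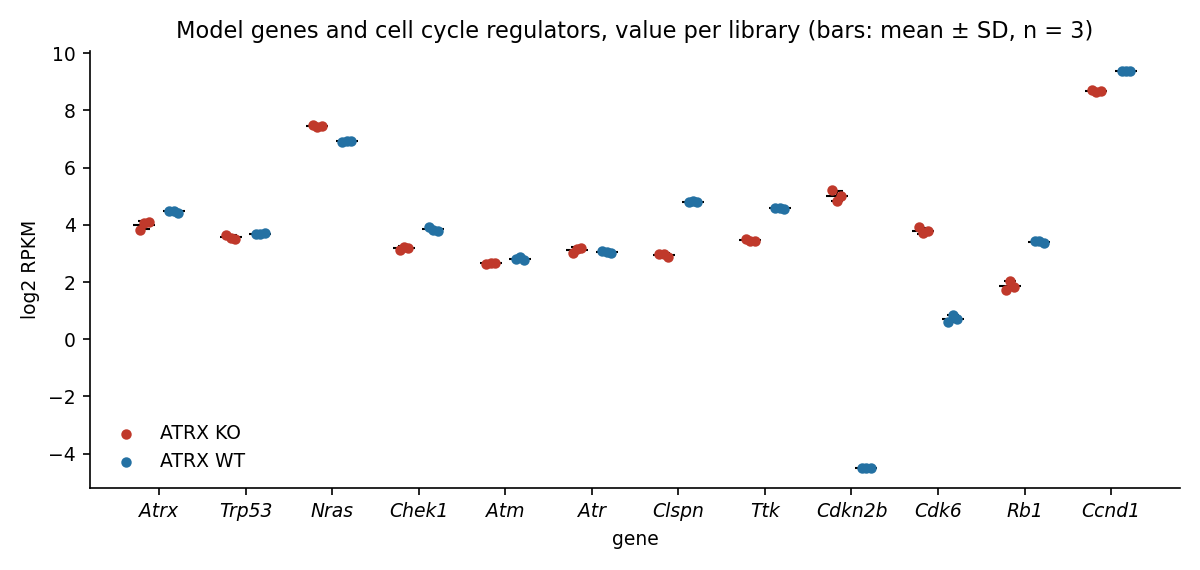
Log2 RPKM of model and cell cycle genes in each library, with points for the 3 ATRX KO and 3 ATRX WT libraries and bars for the mean and SD. Chek1 lay at 3.18 in ATRX KO against 3.84 in ATRX WT, and Cdkn2b at 5.01 against -4.50, the value of a gene with 0 reads.

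Across all genes the groups differed widely. Among the largest rises in ATRX KO were genes of the extracellular matrix. Col3a1, a fibrillar collagen (ENSMUSG00000026043.18), went from log2 RPKM -4.23 ± 0.52 to 9.50 ± 0.09, with 310130 reads against 29 (log2 fold change 13.73, SE 0.216, adjusted p = 7.6e-11). Postn, a matrix protein of fibroblasts, had 53081 reads against 16 (11.77), and the matrix protease Mmp3 20538 against 7 (11.30). Col6a3 (11.21), Mgp (10.55), Bgn (10.30), Col5a2 (10.28) and Thbs2 (10.08) were also among the 10 largest rises. Of the genes named by size, Fabp7, a lipid carrier of radial glia, was among the largest falls. It went from 11.43 ± 0.02 to -2.89 ± 0.64, with 247523 reads in ATRX WT and 4 in ATRX KO (log2 fold change -14.32, SE 0.261). Its ratio of summed reads over summed library sizes was 40600 (95% interval 15800 to 149000). With so few reads in ATRX KO, the order among the largest falls is not resolved.

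Further large falls were read from counts. Olig1, a transcription factor of oligodendrocyte precursors, had 34221 reads in ATRX WT and 0 in ATRX KO, at least 7480-fold lower. Gpm6a, a neuronal membrane protein, was at least 10300-fold lower and Bcas1, a gene of early myelinating cells, at least 4400-fold lower, with 0 reads in ATRX KO. Car3 had 129510 reads in ATRX WT and 2 in ATRX KO, a ratio of 42400 (95% interval 11700 to 350000). For Ptprz1, a receptor phosphatase of oligodendrocyte precursors, the ratio was 15500 (5300 to 75200), and for Nsg2 14400 (3990 to 119000). The glutamate receptor Grm5 gave 21100 (3790 to 835000), Rfx4 11000 (3050 to 91100) and the potassium channel Kcnc1 17800 (3190 to 701000).

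Of 12201 genes tested, 5321 rose and 5604 fell in ATRX KO in limma, 89.5% together. By log2 1 or more, 2102 rose and 2387 fell. A test against a log2 fold change of 1 called 1880 higher and 2100 lower. The 3 ATRX KO values lay wholly above or below the 3 ATRX WT values for 11040 genes, where chance alone gives 10%. The median log2 fold change of all tested genes was -0.02. Scaling by reads in the table in place of the authors' library sizes moved that median by -0.20 and gave 4388 genes higher and 6689 lower, so the balance of rises and falls, and small changes, are relative to the scaling chosen.

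**Figure D2:**
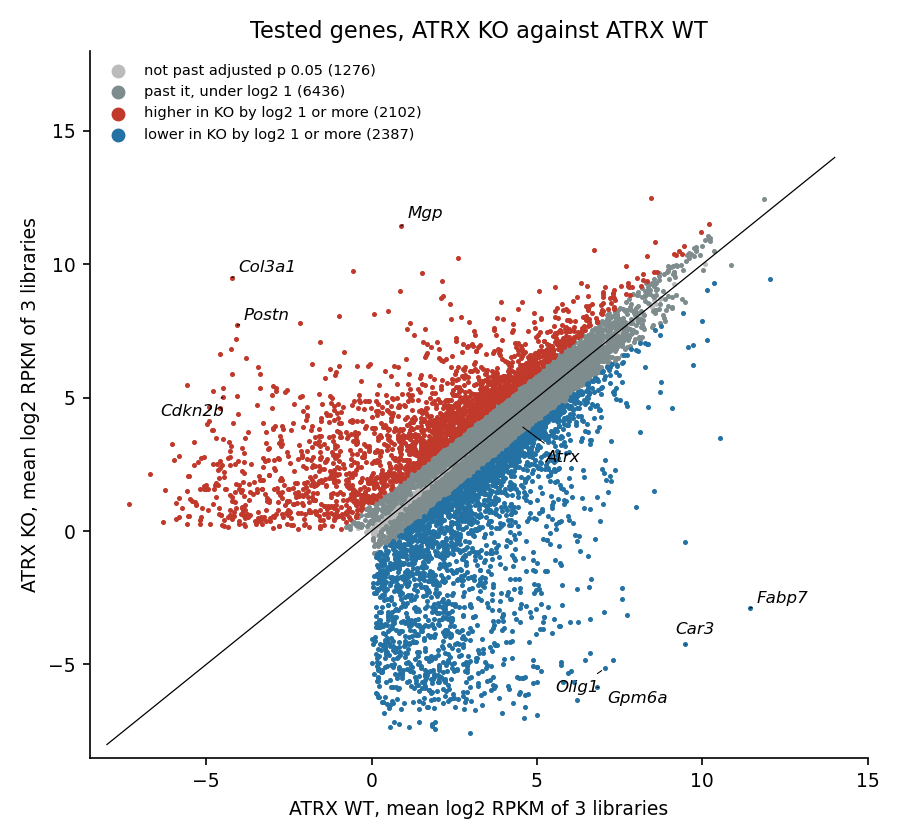
Mean log2 RPKM of each gene in ATRX KO (vertical axis) against ATRX WT (horizontal axis), with genes that rose or fell by log2 1 or more in colour. The named collagen Col3a1 and the glial gene Fabp7 lie far from the diagonal on opposite sides, with log2 fold changes of 13.73 and -14.32.

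Markers of neural cells were low in ATRX KO. All of the neuronal and neuroblast genes that passed fell, 14 of 15 tested, with 0 rises, 1 no call and a median of -3.79 (camera adjusted p = 8.8e-05, and adjusted p = 0.15 with an estimated correlation). The list has 28 members. All 15 tested reached a mean log2 RPKM of 0 in ATRX WT and 6 in ATRX KO, so the filter kept most of them through ATRX WT. Dcx, the microtubule protein of migrating neuroblasts, had 3871 reads in ATRX WT and 0 in ATRX KO, at least 846-fold lower, and the RNA-binding protein Elavl3 fell by 8.65. In the oligodendrocyte lineage 11 of 13 genes tested fell and 2 rose, with a median of -5.17 (adjusted p = 0.0052, and adjusted p = 0.18 with an estimated correlation). Of its 24 members, all 13 tested reached a mean log2 RPKM of 0 in ATRX WT and 4 in ATRX KO. The rises were the growth factor receptor Pdgfra (3.21) and the proteoglycan Cspg4 (2.06), which mark mesenchymal cells as well. Neural stem cell genes gave 16 falls and 5 rises of 21, with a median of -1.69 (adjusted p = 0.014, and adjusted p = 0.17 with an estimated correlation). Lhx2, a forebrain transcription factor, had 1 read against 2415, a ratio of 1580 (284 to 62500), while Gli3 and Gli2, effectors of Hedgehog signalling, rose by 3.28 and 2.67. That list gave adjusted p = 0.053 with scaling by reads in the table, in a range of 0.002 to 0.17. Astrocyte genes gave 13 falls and 5 rises of 18 with a median of -1.80 and did not pass at adjusted p = 0.05, rounded, though p was 0.039 without ATRX KO replicate 2, 0.044 without ATRX KO replicate 1 and 0.048 without ATRX WT replicate 1, in a range of 0.028 to 0.18. With an estimated correlation the astrocyte list had adjusted p = 0.18. The folate enzyme Aldh1l1 fell by 10.12 and Mlc1 was at least 337-fold lower at 0 reads, while the gap junction gene Gja1 and Clu rose by 3.23 and 2.97.

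Matrix and mesenchymal genes were high. Of 31 tested, 29 rose and 2 fell, with a median of 3.75 (adjusted p = 1.5e-08, and adjusted p = 0.15 with an estimated correlation). In ATRX WT 21 of the 31 reached a mean log2 RPKM of 0, and in ATRX KO all 31 did. Col1a1 went from log2 RPKM -0.99 to 8.06, a rise of 9.05. The falls were Zeb1 (-1.83), a repressor of epithelial genes, and the neural cadherin Cdh2 (-1.70). Of 10 pericyte and fibroblast markers 9 rose and 1 fell, with a median of 8.27 (adjusted p = 0.0019, and adjusted p = 0.17 with an estimated correlation). Of that list's 16 members, 7 also stand in another list, and of the 10 tested 2 reached a mean log2 RPKM of 0 in ATRX WT and 9 in ATRX KO. Col3a1 and Postn led the rises, and Rgs5, a pericyte gene, fell by 8.01. Endothelial markers gave 5 rises and 1 fall of 6 with a median of 2.96, and did not pass (adjusted p = 0.12, and adjusted p = 0.32 with an estimated correlation). The endothelial cadherin Cdh5 rose by 7.19 and Emcn by 5.41, while Esam fell by 4.28. Of 20 microglia and macrophage markers 3 were tested and rose, namely Tmem119 (6.04), Cd14 (3.15) and, named after its value was seen, Cd68 (2.25). Both ependymal genes tested, Foxj1 and Rsph1, fell, by 4.63 and 2.99. Of the lymphocyte genes Lck rose by 0.46 and Klrb1c fell by 5.40.

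**Figure D3:**
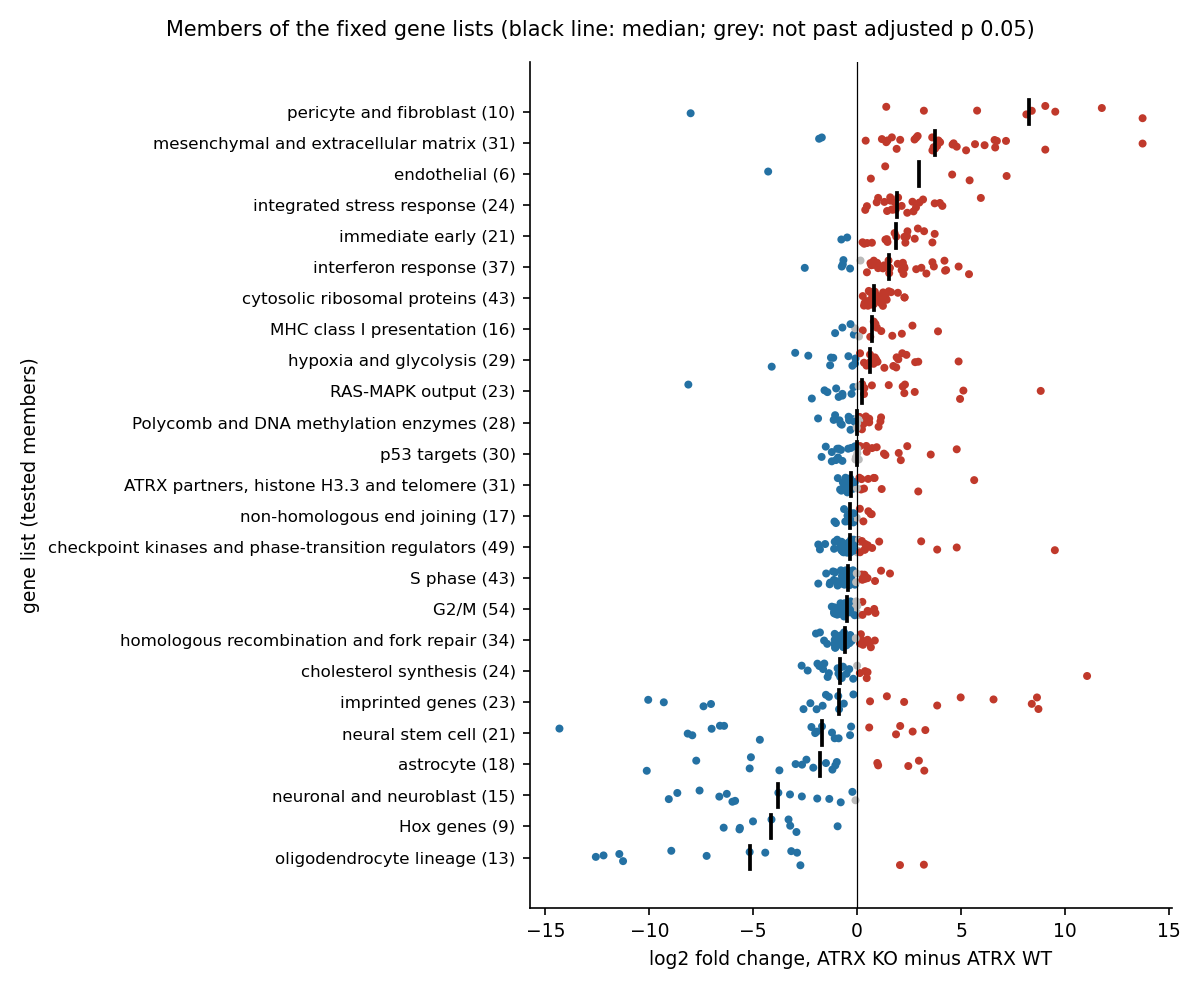
Log2 fold changes, ATRX KO minus ATRX WT, of the tested members of each gene list, with a point per gene and a bar at the list's median. Medians ran from -5.17 for the oligodendrocyte lineage to 8.27 for pericyte and fibroblast markers, against -0.42 for S phase and -0.50 for G2/M.

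Genes of homologous recombination were lower, and p53 targets went both ways. In homologous recombination and fork repair 24 of 34 genes fell, 9 rose and 1 gave no call, with a median of -0.60. Fanci, of the Fanconi anaemia pathway, fell by 1.98 (SE 0.078) and the nuclease Dna2 by 1.79 (SE 0.048), while Xrcc3 and Fance rose by 0.85 and 0.66. The list passed camera (adjusted p = 0.024) but had adjusted p = 0.20 with an estimated correlation, 0.11 after quantile normalization and 0.057 without genes on chromosomes 4 and 16, in a range of 0.013 to 0.20 over camera alternatives. Non-homologous end joining gave 11 falls, 5 rises and 1 no call of 17, with a median of -0.33 and adjusted p = 0.38 (adjusted p = 0.55 with an estimated correlation). Xrcc4 fell by 1.09 and the kinase Prkdc by 1.02, while Xrcc6 rose by 0.70. Of 30 p53 targets 12 rose, 13 fell and 5 gave no call, with a median of -0.03, a mean of 0.28 and adjusted p = 0.99 by both correlations. Plk3 and the death receptor Tnfrsf10b (3.54) rose most, and Trp53inp1 (-1.71) and Pmaip1 (-1.51) fell most.

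Chromatin and telomere genes went both ways, while the tested Hox genes fell. Of 31 ATRX partners, histone H3.3 and telomere genes 10 rose, 20 fell and 1 gave no call, with a median of -0.31 and a mean of 0.11 (adjusted p = 0.27, and adjusted p = 0.32 with an estimated correlation). Sp100, a nuclear body protein, rose from 6 to 412 reads (5.63) and Tert, the catalytic subunit of telomerase, from 115 to 592 reads (2.94), while Pot1b and Terf2ip of the telomere fell by 0.93 and 0.82. Daxx, the histone chaperone that works with ATRX, was chosen after its value was seen and rose by 0.33. Polycomb and DNA methylation enzymes gave 11 rises, 11 falls and 6 without a call of 28, with a median of 0.00 and adjusted p = 0.99 by both correlations. Ezh1 and Aebp2 rose by 1.15 and 1.12, and Jarid2 and Tet1 fell by 1.88 and 1.13. All 9 Hox genes tested fell, with a median of -4.12 (adjusted p = 0.00059, and adjusted p = 0.18 with an estimated correlation), led by Hoxa6 (-6.42) and Hoxa5 (-5.66), genes of body axis identity. The list has 39 members, and all 9 tested reached a mean log2 RPKM of 0 in ATRX WT against 5 in ATRX KO. Of 23 imprinted genes 9 rose and 14 fell, with a median of -0.87 (adjusted p = 0.51, and adjusted p = 0.53 with an estimated correlation). Slc38a4 rose by 8.72 and H19 by 8.65, and Nnat and Gatm fell by 10.05 and 9.30.

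Interferon-responsive genes were higher in ATRX KO. Of 37 tested, 31 rose, 5 fell and 1 gave no call, with a median of 1.54 (adjusted p = 8.8e-05, and adjusted p = 0.44 with an estimated correlation). Ifi44 went from log2 RPKM -1.29 ± 0.12 to 4.09 ± 0.20 (log2 fold change 5.38, SE 0.112) and the antiviral GTPase Mx1 rose from 20 to 510 reads (4.88). In ATRX WT 26 of the 37 reached a mean log2 RPKM of 0, and in ATRX KO all 37 did. Mx1 lies at 90 to 100 Mb of chromosome 16, where 25 genes with a mean log2 RPKM of at least 3 had a median of 0.8. The DNA sensor cGAS, Mb21d1, fell by 2.52 and Gbp7 by 0.74. Of 16 genes of MHC class I presentation 10 rose, 4 fell and 2 gave no call, with a median of 0.72 (adjusted p = 0.071, and adjusted p = 0.20 with an estimated correlation). H2-T23 rose by 3.89, though reads shared among near-identical H2 genes leave that value uncertain, and the peptide loader Tapbp rose by 2.66. The immunoproteasome subunit Psmb9 and the transporter Tap2 fell by 1.06 and 0.71.

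Stress and immediate early genes rose. All 24 genes of the integrated stress response rose, with a median of 1.92 (adjusted p = 1.5e-08, and adjusted p = 0.15 with an estimated correlation). Cth, which makes cysteine, went from log2 RPKM 1.62 ± 0.21 to 7.58 ± 0.04 (log2 fold change 5.95, SE 0.090), and the stress hormone Fgf21 rose by 4.10. Of 21 immediate early genes 19 rose and 2 fell, with a median of 1.88 (adjusted p = 6.5e-05, and adjusted p = 0.15 with an estimated correlation). Atf3 rose by 3.73 and the growth regulator Myc from 46.4 to 570 RPKM (3.62), while Fos and Jund fell by 0.76 and 0.48. Myc lies at 60 to 70 Mb of chromosome 15, where 10 genes with a mean log2 RPKM of at least 3 had a median of 1.25 (25th percentile 0.88). Those are fewer than the 20 genes required of a stretch in the comparison along the genome. RAS-MAPK output genes, which the Nras oncogene drives, went both ways, with 12 rises, 10 falls and 1 no call of 23 and a median of 0.24 (adjusted p = 0.52, and adjusted p = 0.54 with an estimated correlation). Il1rl1 had 2411 reads against 1, a ratio of 3680 (660 to 145000), and Epha2 rose by 5.11, while Epha4 was at least 439-fold lower and the feedback inhibitor Spry1 fell by 2.18. Epha2 lies at 140 to 150 Mb of chromosome 4, where 30 genes with a mean log2 RPKM of at least 3 had a median of 1.23. Hypoxia and glycolysis genes gave 19 rises and 10 falls of 29, with a median of 0.63 (adjusted p = 0.068, and adjusted p = 0.52 with an estimated correlation). That list passed without ATRX WT replicate 1 (adjusted p = 0.048) and with scaling by reads in the table (0.036), in a range of 0.036 to 0.52. Car9 and Ero1l rose by 4.88 and 2.94, and Adm and Pfkfb3 fell by 4.11 and 2.98. With the preset correlation 14 of the 25 lists tested passed, and with an estimated correlation 0 did, where the lowest adjusted p was 0.15. Among the lists that passed, the estimate was -0.013 for neuronal and neuroblast genes and -0.031 for neural stem cell genes, under the preset 0.01. The others had estimates of 0.022 to 0.533. A call lost in that setting is therefore not in itself evidence of correlation between the genes of a list.

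Position along the genome was examined after the values were seen, on the 7039 genes with a position and a mean log2 RPKM of at least 3. Those on chromosomes 4 and 16 had medians of 0.61 and 0.59, against -0.16 to 0.23 on each other chromosome. Among 136 bins of 10 Mb with at least 20 genes, 7 had a median of 0.75 or more, 4 on chromosome 4 and 3 on chromosome 16. The highest stood at 150 to 160 Mb of chromosome 4 with a median of 1.47, and on chromosome 16 at 30 to 40 Mb with 1.11. By contrast 120 to 130 Mb of chromosome 4, which holds Clspn, had a median of -0.40, and 10 to 20 Mb of chromosome 16, which holds Prkdc, had a median of -0.55 over 51 genes. Of the 232 genes in the 7 higher bins 86.6% rose, against 48% elsewhere. That share was bound to be high, since the bins were picked by the medians of the same genes. With bins picked on a random part of the genes, 83.1% of the remaining genes in them rose (median of 100 draws, 5th to 95th percentile 75.9 to 90.3).

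**Figure D4:**
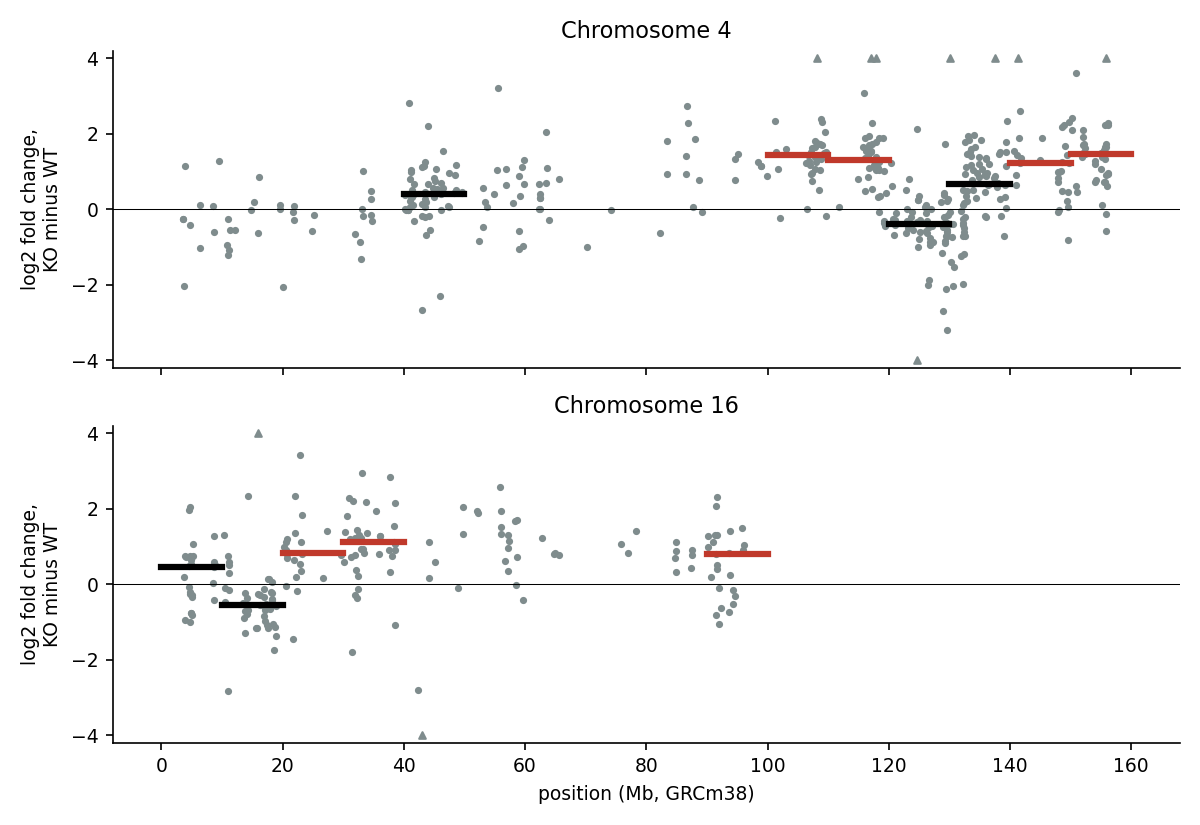
Log2 fold change, ATRX KO minus ATRX WT, of genes with mean log2 RPKM of at least 3 against position (Mb, GRCm38) on chromosomes 4 and 16, with grey points for genes and triangles for those beyond 4 either way. Bars are medians of 10 Mb bins with at least 20 genes, red where the median is 0.75 or more, as in 4 bins of chromosome 4 and 3 of chromosome 16.

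Sex and strain genes were read as a check on the source animals. Xist, the RNA that silences an X chromosome in female cells, was present in both genotypes at log2 RPKM 6.13 ± 0.11 in ATRX KO and 6.34 ± 0.04 in ATRX WT (log2 fold change -0.21, adjusted p = 0.0035). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty are not in the table. Nnt, a mitochondrial transhydrogenase (chromosome 13, 119335448 to 119408997), stood at 20.5% of the ATRX WT level, in RPKM, in ATRX KO (log2 fold change -2.29, SE 0.056, adjusted p = 8.4e-10).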

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

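Voom on recovered reads, scaling by reads in the table, thinned reads and the fit without chromosomes 4 and 16 are tests chosen after the result was seen. Over all alternatives Atrx was lower by a log2 fold change of -0.68 to -0.39, and between 3980 and 11694 genes passed. Leaving out 1 library gave 10645 to 10947 genes, 5201 to 5329 higher and 5444 to 5618 lower, 2093 to 2108 higher and 2362 to 2396 lower by log2 1 or more, and Atrx at -0.53 to -0.39. The limma camera adjusted p then ran from 0.0048 to 0.0089 for S phase, from 0.00011 to 0.00031 for G2/M and from 0.075 to 0.092 for checkpoint genes. With the replicate number as a block, 10806 of 10925 calls were kept and 119 lost. Deviations of equally numbered libraries correlated at -0.05, 0.05 and -0.04, so the numbers show no pairing. Quantile normalization lost 736 calls and called 117 genes the opposite way, and scaling by reads in the table lost 853 and called 80 the opposite way. The other alternatives that refit all genes called 0 the opposite way.

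A filter at log2 RPKM 2 left 1580 genes lower by log2 1 or more, since fewer genes were tested. The test against a log2 fold change of 1 called 3980 genes, 1880 higher and 2100 lower, by its stricter construction. Checkpoint genes passed with the filter at log2 RPKM 2 (adjusted p = 0.049), after quantile normalization (0.018), with scaling by reads in the table (0.046) and in fry, which does not compare with other genes (0.00012 directional, 2.1e-08 mixed), in a range up to 0.32; the cause was not tested. S phase and G2/M did not pass with an estimated correlation (adjusted p = 0.18 and 0.15), their highest values; the cause was not tested.

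Direction turned, with no call, for these lists in some settings; the cause was not tested. Polycomb gave camera p values of 0.88 with no filter, 0.98 with the stricter filter, 1 with log2(RPKM + 1), 1 with trimmed mean scaling, 0.87 without chromosomes 4 and 16, and 0.99 without ATRX KO replicate 2 or 3. The p53 targets gave 0.73 with the stricter filter, 0.99 with the replicate block, 0.93 with voom, 0.99 with thinned reads, 0.92 without chromosomes 4 and 16, 0.99 without ATRX KO replicate 1 or 3, and 1 without ATRX WT replicate 2. Over all 6 fits with a library left out, including those that kept the direction, each list ran from 0.95 to 1. Atr turned to -0.12 with scaling by reads in the table, which moved the median of all tested genes by -0.20. Depth limits genes near 0 reads, most in ATRX KO replicate 3, the library with the fewest reads.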

Other observations

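Tests chosen after the result was seen are those along chromosomes 4 and 16, the mixing and lineage tests and the split test of large changes, and the others, though some were devised after the table had been seen, were written before their own values were computed. Cholesterol synthesis genes were lower in ATRX KO. Of 24 tested, 18 fell, 5 rose and 1 gave no call, with a median of -0.81 (camera adjusted p = 0.0052, and adjusted p = 0.24 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell from log2 RPKM 6.91 ± 0.03 to 4.53 ± 0.04 and Tm7sf2 fell by 2.67. Idh1, chosen after its value was seen, fell by 2.51.

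Cytosolic ribosomal protein genes rose, all 43 tested, with a median of 0.82 (adjusted p = 1.1e-08, and adjusted p = 0.25 with an estimated correlation). Rps6 rose by 2.28, and reads shared with processed pseudogenes leave single values uncertain. The 6 members on chromosomes 4 and 16 had a median of 1.58 and the 37 elsewhere 0.77. Mitochondrially encoded genes are not in the table, so RNA quality was not read from them. Zero-read genes numbered 292, 333 and 361 in ATRX KO libraries and 57, 45 and 63 in ATRX WT libraries. The glycolytic enzyme Gapdh, often used as a control gene and chosen after its value was seen, was higher by 0.79. Lists of transcription factors and fibroblast markers were added after the table was seen. Of 26 neural transcription factors tested 21 fell and 5 rose, and of the list's 32 members 12 stand in another list. Of 19 mesodermal and fibroblast factors 14 rose and 5 fell (median 2.27), and of 11 meningeal fibroblast genes 8 rose and 3 fell (median 4.51), each list sharing 3 members with another. In ATRX WT 12 of the 19 and 5 of the 11 also reached a mean log2 RPKM of 0. All 26 tested neural factors reached it in ATRX WT and 13 in ATRX KO.

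Stromal transcripts stood in place of neural ones in ATRX KO. Lower depth is argued against, since after thinning to equal depth ATRX KO still had 4.63 times as many zero-read genes. Stromal cells added to a culture like ATRX WT would lower all neural factors by a similar amount, but their log2 fold changes had an interquartile range of 6.85, and Fabp7, Olig1 and Gpm6a kept 4, 0 and 0 reads; an earlier bound on the median left this undecided, and mixing with another neural culture, or near-complete replacement by cells that express the remaining factors, is not excluded. A line of another lineage stays open, as the median of -3.32 for neural factors comes from a list made after the pattern was seen, and single genes, chosen after their values were seen, went both ways, with Sox2 down from 80.4 to 19.8 RPKM but the neural factors Emx2 (1.87) and Zic1 (0.77) up and the usual partner of Col1a1, Col1a2, at 0.635 RPKM. Another lineage and loss of ATRX cannot be told apart, because each genotype has 1 line code.

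Genes in stretches of chromosomes 4 and 16 were higher in ATRX KO as blocks. Chance placement is argued against, as the highest bin median in 1000 shuffles was 1.08 against 1.47 observed, and at most 1 bin was called in a shuffle against 7. So are a few strong genes in the pooled stretches, since with bins picked on one part of the genes, drawn at random 100 times, the 25th percentile of the remaining genes was 0.5 (5th to 95th percentile 0.17 to 0.81) against a median of 0.06 elsewhere, but at 90 to 100 Mb of chromosome 16 the 25th percentile was -0.14, so for that stretch it stays open. A difference in DNA copy number between the lines remains a candidate explanation, with 83.1% of genes rising (75.9 to 90.3) around a bound of 80 set for it, so it cannot be told apart from regional regulation without DNA data. Loss of ATRX stays open and untested here, as line and genotype coincide.

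Nnt was lower in ATRX KO. Fewer copies of its region are argued against, as the 8 other tested genes within 2 Mb had a median of -0.21, including, singled out after their values were seen, adjacent Paip1 at -0.24 and Mrps30 at 0.74, although Ccl28 (-1.65), Hmgcs1 (-2.38) and Nim1k (-3.19) fell. Another mouse strain as the source of the ATRX KO line could give the log2 fold change of -2.29, since some C57BL/6 substrains carry a deletion within Nnt, but the labels give no strain per line and exons cannot be read from a gene total, so this stays open. Loss of ATRX as its cause was not tested.

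The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split called 10925 genes and 4489 by log2 1 or more in limma, and 1 of the 10 splits, the real one, gave as many of either. The highest other split called 0, with 0 to 2 genes at an unadjusted p under 0.05. Every other split mixes both lines within each group, so the difference between lines adds to the spread there. Few calls in those splits were therefore fixed in advance and do not bear on chance.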
